A study of Mus musculus with 14 samples.

How the data were processed

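The series holds single-cell RNA counts of spiral ganglion neurons, the afferent neurons of the cochlea, from CD1 mice at embryonic day 14, 16 and 18 (E14, E16, E18) and postnatal day 1 (P1). Per the labels, ganglia were dissected with some sensory epithelium and mesenchyme attached, pooled by litter, and run as droplet libraries with 3 biological replicates at each embryonic age and 2 at P1. At E16 the ganglia were divided at the middle turn, which gives 3 apical and 3 basal libraries and 14 libraries in all. Per the labels, tissue was dissociated with trypsin at E14 and E16 and with papain at E18 and P1, so the enzyme changes together with age. The labels name Cell Ranger 3.0.1 and Seurat 3.2 and the mm10 build, and do not state which filters on cells or doublets were used.

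The deposited count table holds UMI counts (unique molecular identifiers) per gene and cell, with no normalization by the authors. The second deposited table holds log-normalized values (ln), the natural log of 1 plus the count per 10000 UMIs of the cell, made by the authors. The count table ends after 17999 of the 26655 genes of the normalized table. The counts of the other 8656 genes, 32.5% of the genes and 28.2% of all UMIs, were computed back from the normalized table. Every recovered value was a whole number within 0.001, and 0 entries of the shared genes differed between both tables. Cells were given to libraries by the number at the end of the cell name, matched to the sample number in the descriptions, a mapping that the labels do not state in words. All 5441 deposited cells were kept, and no doublet caller was run. Of the gene symbols, 25529 were found in the GENCODE annotation of the mm10 build.

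Comparisons of ages used UMI counts summed over the cells of each biological replicate, with the E16 portions of 1 replicate number summed. Sums were compared with quasi-likelihood tests in edgeR 4.0.16 (TMM normalization, filterByExpr, all ages in 1 fit, Benjamini-Hochberg adjusted p under 0.05). Apical and basal libraries at E16 were compared in a fit of their own. Pairing was checked for these libraries: profiles of apex and base, each centred on its portion, correlated best with the portion of the same replicate number for each of the 3 numbers (0.465, 0.303 and 0.496). The main comparison of apex and base had no block by replicate number, and the blocked fit was an alternative. Replicate numbers of different ages are different litters, so a replicate block has no meaning there beyond a check. Standard errors (SE) are the log2 difference divided by the square root of the F statistic. CPM is the UMI count of a gene over the total of the summed profile, as the cpm function of edgeR gives it, and SD is the standard deviation over replicates.

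Named genes follow a rule. In each comparison of ages or positions they are the 10 largest log2 differences in each direction among genes past the threshold, with a mean of at least 20 CPM in the higher group and with no overlap of replicates between groups. Groups of 3 against 3 fail to overlap by chance in 10% of genes. Mitochondrial, ribosomal protein, haemoglobin, Xist, Tsix and Y-linked genes and unnamed gene models were left out. Not every gene that the rule takes is printed. In each comparison of subtypes the 5 largest in each direction at E16 and P1 were taken. From each gene list up to 4 members with the smallest adjusted p were taken. The rule, the lists, the comparisons and most alternatives were fixed before the data were examined.

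Gene lists were tested with camera in limma 3.58.1 at the preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over all lists and contrasts of a design. The lists cover synaptic vesicles and release, glutamate receptors and transport, voltage-gated sodium channels, voltage-gated potassium channels, HCN and calcium channels, axon guidance, neurotrophin and GDNF receptors, neurofilament and axonal cytoskeleton, neuronal transcription factors, immediate early and stress genes, cholesterol synthesis, glycolysis, cell cycle, BMP, Notch and FGF signalling, adhesion and cadherins, calcium-binding proteins, and retinoid and thyroid signalling. Marker lists cover neurons, spiral ganglion neurons, subtypes IA, IB/IC and II, neuroblasts, cycling cells, geniculate neurons, glia, otic mesenchyme, hair cells, supporting epithelium, endothelium, red blood cells, macrophages and melanocytes. A list needed at least 3 tested members.

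Subtype scores were the mean over the list genes of log counts after thinning each cell to 5000 UMIs, which leaves out shallower cells. Their Spearman correlation across cells was taken per replicate, compared with random gene lists of matched expression, and tested over replicates with exact two-sided permutation tests. For the class comparisons, a cell was placed in a list class when its standardized score led the other scores by at least 0.5, a range drawn on a continuous score rather than a separate population. Genes outside the lists were compared between classes with edgeR, with the library as a block, in libraries with at least 10 cells in both classes. At E16 the apical and basal libraries entered as separate blocks, although they are portions of 3 biological replicates. The E16 class fits thus treat portions of 1 replicate as independent. Clusters were made per age with Leiden in scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, resolution 1). Before clustering, the mean of each library was subtracted from each gene. At E16 this also takes out part of any difference between apical and basal libraries, so the cluster shares depend on it. Intervals of shares are exact Clopper-Pearson intervals at 95%, and with floors of 3 counts they cover counting error only.

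Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, deeper cells, a replicate block, equal cell numbers, other margins and resolutions, and each replicate left out in turn. RLE scaling moved the median of all genes by 0.03 on the log2 scale at most in the comparisons of ages and positions. With simulated changes of 2 on the log2 scale in 200 genes, the edgeR fits recovered 98.0% between E16 and E14, 100% between E18 and E16, 100% between P1 and E18 and 100% between apex and base. At a change of 1 the shares were 82.0%, 66.0%, 50.0% and 85.0%, and 10 of 190, 11 of 177, 18 of 168 and 10 of 195 calls were false. Between classes at P1, 39.0% and 85.4% were recovered for type II against type I, and 50.6% and 96.6% for type IA against type IB/IC. Both P1 simulations took the variability of genes from the E16 comparison of type IA with type IB/IC. They therefore do not show how the fits handle the spread of the P1 libraries. A list raised in the simulated data had a camera p of 8.53e-08, and 1 of 100 random lists fell under 0.05. The simulated genes were drawn without correlation between them, so this does not test false list calls that come from correlated genes. Libraries held 162 to 734 cells and 1327692 to 3819454 UMIs.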

Results

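The data describe 5441 spiral ganglion neurons and 34122909 UMIs from 14 libraries. E14 gave 1637 cells, with 524, 379 and 734 in its 3 replicates and totals of 2892393, 2155727 and 3819454 UMIs. E16 gave 2478 cells, of which the apical libraries held 328, 544 and 496 (1812324, 3435044 and 3141701 UMIs) and the basal libraries 235, 466 and 409 (2227921, 1327692 and 2846658 UMIs). E18 gave 862 cells, with 377, 323 and 162 per replicate and 3026607, 1542607 and 1460876 UMIs. P1 gave 464 cells, with 263 and 201 in its 2 replicates and 2886279 and 1547626 UMIs. The median depth per cell was 4961 UMIs at E14, 5885 at E16, 6939 at E18 and 10064 at P1, and single libraries ranged from 2769 (E16 base replicate 2) to 11440 (P1 replicate 1). RNA of blood cells reached the droplets: the haemoglobin gene Hbb-bs had at least 1 UMI in 5.47% to 90.6% of neurons per library.

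The comparison of E16 with E14 asks what changed in the summed cells as neurons leave the neuroblast stage. Calb2, the calcium-binding protein calretinin, rose from 1.20 ± 1.10 CPM (SD, n = 3) at E14 to 135 ± 98.2 CPM (n = 3) at E16, a log2 difference of 6.70 (SE 0.59, adjusted p = 2.1e-06). Necab1, another neuronal calcium-binding protein, rose by 5.32 on the log2 scale (SE 0.30) to 55.6 ± 10.5 CPM. Mfap4, a protein of the extracellular matrix, fell from 178 ± 87.3 to 3.39 ± 0.519 CPM, a log2 difference of -5.75 (SE 0.34, adjusted p = 7.2e-08). Gldn, gliomedin of the nodes of Ranvier, had 2 counts in all E14 replicates and 384 at E16, a ratio of 115 with a counting interval of 31.6 to 954. In total 1771 of 12547 tested genes passed, 1003 higher and 768 lower at E16.

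The other genes with the largest rises between E14 and E16 were Pappa, a protease of insulin-like growth factor binding proteins (log2 4.88, SE 0.39), the extracellular matrix protein gene Npnt (4.76, SE 0.34), the phospholipase Plcb1 (4.76, SE 0.32), the homeobox gene Prrx2 (4.68, SE 0.29), Pdzd2 (4.62, SE 0.43), the synaptotagmin Syt17 (4.42, SE 0.30) and Slc35f4 (4.32, SE 0.43). Large falls were those of Rd3 (-6.60, SE 0.56), Ppp1r17, an inhibitor of protein phosphatases (-6.05, SE 0.46) and the cardiac actin gene Actc1 (-6.04, SE 0.54). Further falls were those of Ccdc88b (-4.69, SE 0.41), Ppp1r14a (-4.69, SE 0.36), Lmod1 (-4.24, SE 0.46), Ccer2, a gene of the hair cell list (-4.19, SE 0.47), and the secreted guidance cue Sema3c (-4.11, SE 0.39). Ppp1r17 went from 155 ± 71.9 to 2.36 ± 2.04 CPM (n = 3 each). Each of these genes passed the threshold in edgeR whichever replicate was left out, and in DESeq2. Mfap4, Ppp1r17, Ppp1r14a, Ccdc88b and Actc1 also marked a cluster named neuroblast, 324 of the 1637 cells at E14. No cluster at E16 was named so. The falls of these genes in the summed counts cannot tell fewer such cells from change within cells. Calb2 lies on chromosome 8 from 110137502 to 110168210, annotated as protein coding in mm10.

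Among the gene lists, those of neuroblasts, cell cycle, cholesterol synthesis and neuronal transcription factors fell between E14 and E16. All 5 tested neuroblast markers fell, among them Eya2 (log2 -3.81, SE 0.38), Neurod1 (-3.71, SE 0.41) and Nhlh1 (-3.54, SE 0.44), which act in the differentiation of sensory neurons. The list had an adjusted p of 1.4e-07 in camera, and adjusted p = 0.262 with an estimated correlation. Of 17 cell cycle genes 6 fell, 8 adjusted over the list alone. Ccnd1, cyclin D1, was at -2.49 (SE 0.23, list adjusted p = 3.3e-04, 0.351 with an estimated correlation). Of 33 neuronal transcription factors 16 fell and 8 rose, 17 and 9 adjusted over the list alone, with Meis2 at -2.90 (SE 0.37) and Zeb2 at -2.37 (SE 0.31). This list had adjusted p = 0.0120, and adjusted p = 0.454 with an estimated correlation. Of 18 cholesterol genes 3 fell, among them Insig1 (-0.92, SE 0.26) and Dhcr7 (-0.83, SE 0.25), 8 adjusted over the list alone, with adjusted p = 0.00126 for the list and 0.454 with an estimated correlation. The red blood cell list fell too (adjusted p = 0.0372, and 0.539 with an estimated correlation), with 1 of 3 genes past the threshold, 2 adjusted over the list alone, and Hba-a1 at -1.57 (SE 0.37).

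Lists of synaptic vesicle, glutamate, potassium channel, and HCN and calcium channel genes passed as higher at E16 than at E14 in camera at its preset correlation. Of 24 synaptic vesicle genes 9 rose and 2 fell, 10 and 3 adjusted over the list alone, with the calcium sensor Syt7 at 2.71 (SE 0.20), the active zone scaffold Rims1 at 1.92 (SE 0.21) and Sv2c at -2.38 (SE 0.28). The list had adjusted p = 0.00269, and adjusted p = 0.483 with an estimated correlation. Of 21 potassium channel genes 7 rose and 1 fell, counts that were equal adjusted over the list alone. Kcnt1 was at 2.68 (SE 0.35) and Kcnq3 at 1.85 (SE 0.21), and the list had adjusted p = 0.00496, and 0.565 with an estimated correlation. Of 16 HCN and calcium channel genes 6 rose and 0 fell, 7 adjusted over the list alone. Cacna1d, the Cav1.3 channel, was at 3.12 (SE 0.44), and the list had adjusted p = 0.0446, and 0.351 with an estimated correlation. Of 14 glutamate receptor and transport genes 6 rose and 3 fell, 7 and 3 adjusted over the list alone, with Gria3 at 1.98 (SE 0.21), Gria2 at 1.28 (SE 0.17) and Grin2a at -2.28 (SE 0.31). The glutamate list had adjusted p = 0.0476, and adjusted p = 0.538 with an estimated correlation. Of 6 type IA markers 3 rose and 0 fell, 4 adjusted over the list alone. Calb2 was at 6.70 (SE 0.59) and Mdga1 at 1.29 (SE 0.29), with list adjusted p = 0.00189, and adjusted p = 0.262 with an estimated correlation. Glycolysis, with 5 of 18 genes up and 6 adjusted over the list alone, had a median log2 difference of 0.11, with Eno2 at 1.72 (SE 0.19), list adjusted p = 0.0484, and adjusted p = 0.454 with an estimated correlation.

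Genes listed as markers of other cells moved with age as well. Dcn, decorin of mesenchyme, rose by 3.03 (SE 0.30) and S100b, which glia and some neurons express, by 3.73 (SE 0.41) on the log2 scale between E14 and E16, while the mesenchyme gene Twist1 fell (-1.62, SE 0.32). At E16 Dcn also marked a cluster of 501 cells named type IA, and S100b a cluster of 428 cells named type IB/IC. Neither gene is thus a sign of other cells alone in these data. The count of 1771 fell to 1150 without E14 replicate 2, to 1169 without E14 replicate 3 and to 1008 with cells of at least 5000 UMIs. No list kept its call with an estimated correlation, the lowest adjusted p being 0.262.

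Other lists did not pass between E14 and E16. Type II markers had 4 of 7 higher and 1 lower, 5 and 1 adjusted over the list alone, with Th at 3.18 (SE 0.41) and list adjusted p = 0.0880. Sodium channels had 2 of 7 higher, with Scn1a at 1.18 (SE 0.27) and list adjusted p = 0.105. Retinoid and thyroid signalling had 3 of 12 higher and 1 lower, with Aldh1a3 at 3.01 (SE 0.37), Thrb, a thyroid hormone receptor, at 2.39 (SE 0.30) and list adjusted p = 0.210. Axon guidance had 5 of 31 higher and 8 lower, 9 and 11 adjusted over the list alone (adjusted p = 0.625), with the receptor genes Unc5d at 1.41 (SE 0.17) and Nrp2 at -2.56 (SE 0.42). Adhesion had 6 of 28 higher and 6 lower, 7 and 8 adjusted over the list alone (adjusted p = 0.873), with Nrxn3 at -3.21 (SE 0.43). Neurotrophin and GDNF receptors had 3 of 9 higher and 2 lower, 4 and 2 adjusted over the list alone, with Gfra2 at 2.39 (SE 0.37) and list adjusted p = 0.490. The adjusted p was 0.184 for neuron markers (1 of 10 lower, 4 adjusted over the list alone), 0.930 for spiral ganglion neuron markers (3 of 9 higher and 3 lower, 4 and 3 adjusted over the list alone) and 0.874 for type IB/IC markers (2 of 5 higher and 2 lower, 3 and 2 adjusted over the list alone). It was 0.173 for cycling markers (2 of 3 lower), 0.945 for otic mesenchyme (1 of 5 higher and 2 lower, 2 and 2 adjusted over the list alone) and 0.858 for immediate early and stress genes (1 of 18 higher and 2 lower). Median and test differed in sign for neurofilament and axonal cytoskeleton (median -0.05, tested higher, adjusted p = 0.840) and glia (median -0.16, tested higher, 0.85). They also differed for BMP, Notch and FGF signalling (median 0.06, tested lower, 0.873) and calcium-binding proteins (median 0.01, tested lower, 0.898). Hair cell (2 tested), supporting epithelium (2), endothelium (1), macrophage (1), geniculate neuron (0) and melanocyte (0) markers were too few to test as lists. Among them Jag1 of supporting cells was at -2.49 (SE 0.66), the endothelial Pecam1 at 0.08 (SE 1.03) and the macrophage gene C1qb at -2.19 (SE 0.70). Both tested hair cell markers were lower, Myo6 at -0.64 (SE 0.20) and Ccer2 at -4.19 (SE 0.47).

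**Figure D1:**
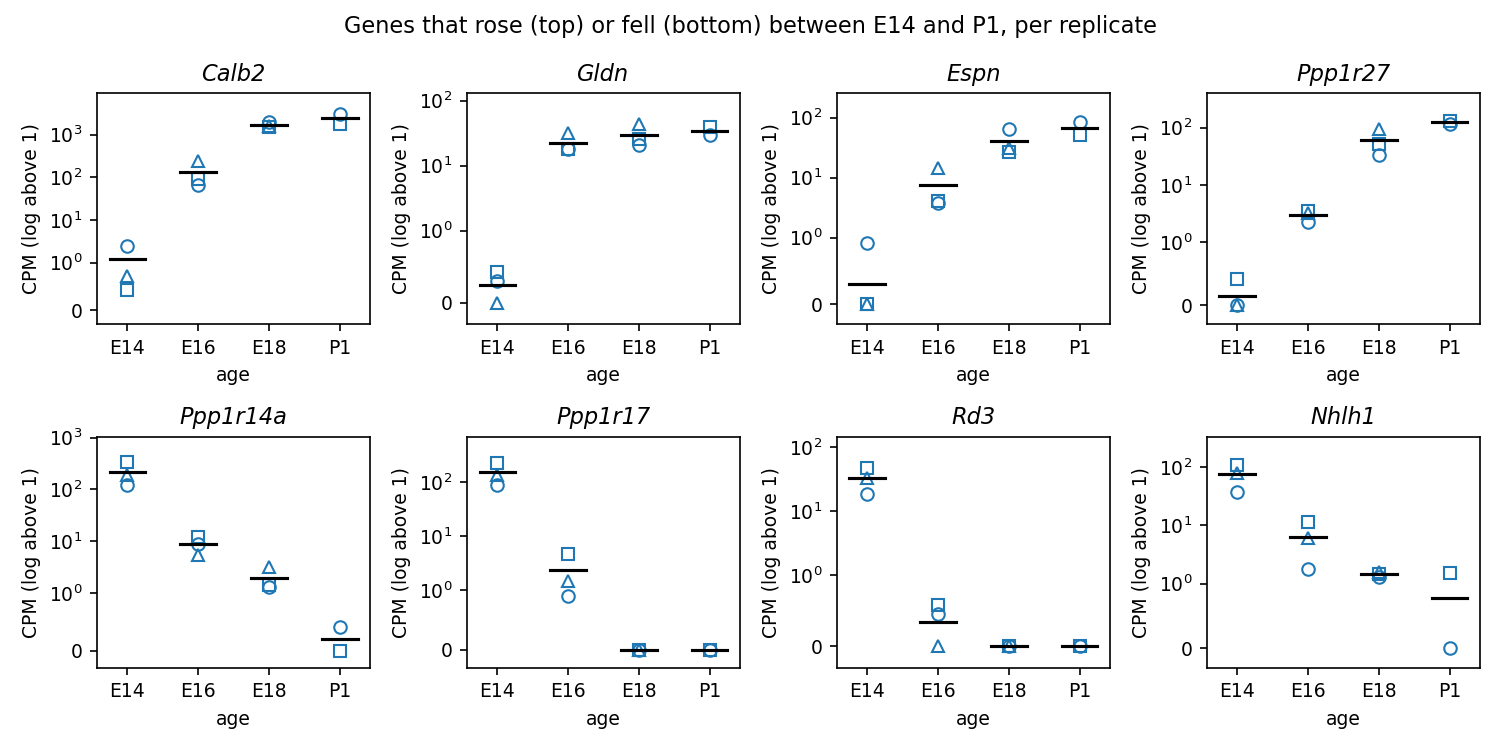
Expression in CPM (y axis, log scale above 1) of 8 genes by age (x axis), with 1 marker per replicate (circle, square and triangle for replicates 1, 2 and 3) and a bar for the mean. Calb2 went from a mean of 1.20 CPM at E14 to 135 at E16, 1667 at E18 and 2440 at P1, while Rd3 went from 33.4 at E14 to 0.346 at E16.

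The comparison of E18 with E16 covers the last days before birth, and also a change of enzyme from trypsin to papain. Calb2 rose again, from 135 ± 98.2 to 1667 ± 240 CPM (n = 3 each), a log2 difference of 3.69 (SE 0.41, adjusted p = 2.9e-04). Ppp1r27 rose by 4.31 (SE 0.37) to 60.4 ± 32.4 CPM, the muscle-type myosin light chain gene Myl1 by 3.33 (SE 0.48) to 91.3 ± 73.6 CPM, Fabp3, a carrier of fatty acids, by 2.69 (SE 0.31) to 310 ± 148 CPM and Espn, the actin bundler espin, by 2.51 (SE 0.45) to 41.0 ± 21.3 CPM. Among genes that fell were Uts2b, a peptide of the urotensin family, from 31.0 ± 19.5 to 6.12 ± 3.43 CPM (log2 -2.40, SE 0.51), and Rgs4, a regulator of G protein signalling, from 25.6 ± 10.4 to 4.96 ± 2.75 CPM (log2 -2.10, SE 0.37). In total 2052 of 12547 genes passed, 1207 higher and 845 lower at E18.

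Further rises at E18 were those of the chemokine Ccl21a (log2 3.24, SE 0.49), the small GTPase Rem2 (2.99, SE 0.55), Pgk1 of glycolysis (2.92, SE 0.71), Atp5l (2.70, SE 0.47) and Bloc1s1 (2.60, SE 0.56). Ccl21a, Pgk1 and Atp5l have near-identical copies or pseudogenes in the genome, so their counts depend on how shared reads were handled. Pgk1 lost its call without E16 replicate 2 (adjusted p = 0.062), E16 replicate 3 (0.064) or E18 replicate 2 (0.162), and Bloc1s1 without E18 replicate 2 (0.065). Further falls were those of Tmie (-1.74, SE 0.40), Igfbp2 (-1.70, SE 0.28), Spock1 (-1.70, SE 0.27), Gas1 (-1.64, SE 0.30), Ccdc177 (-1.62, SE 0.24), the kinase Prkg1 (-1.59, SE 0.25), the alpha-catenin Ctnna1 (-1.59, SE 0.24) and Rnf150 (-1.58, SE 0.20).

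Glycolysis genes rose together between E16 and E18, with 13 of 18 past the threshold and a median log2 difference of 0.75. Eno1 rose by 1.48 (SE 0.19), Aldoa by 1.46 (SE 0.20), Ldha by 1.34 (SE 0.18) and Aldoc by 1.32 (SE 0.20), and the list had adjusted p = 4.2e-09, and adjusted p = 0.137 with an estimated correlation. Of 15 calcium-binding proteins 6 rose and 0 fell, 6 and 1 adjusted over the list alone. S100b was at 2.23 (SE 0.27), Vsnl1 at 1.77 (SE 0.24) and Calb2 at 3.69, with list adjusted p = 0.00269, and 0.205 with an estimated correlation. Of 31 axon guidance genes 10 fell and 0 rose, 12 adjusted over the list alone. Among them were the semaphorins Sema6d (-2.36, SE 0.35) and Sema3a (-1.48, SE 0.24) and the netrin receptor Unc5c (-1.14, SE 0.21), with adjusted p = 0.00189 for the list and 0.239 with an estimated correlation. Of 33 neuronal transcription factors 10 fell and 1 rose, with Myt1 at -1.11 (SE 0.21), Gata3 at -1.05 (SE 0.22) and Rbfox3, the NeuN protein, at 0.78 (SE 0.17). The list had adjusted p = 0.00894, and adjusted p = 0.454 with an estimated correlation. Of 28 adhesion genes 4 fell and 1 rose. Cdh13 was at -1.51 (SE 0.34) and Cdh9 at 1.58 (SE 0.33), with list adjusted p = 0.0435, and adjusted p = 0.582 with an estimated correlation. All 3 tested markers of red blood cells fell, with Hbb-bt at -3.15 (SE 0.70, adjusted p = 0.00966) and Hba-a1 at -2.30 (SE 0.49). Their list had adjusted p = 0.0957, and no list of this comparison passed in camera with an estimated correlation. Of 5 neuroblast markers 1 fell, 4 adjusted over the list alone, with Nhlh2 at -1.20 (SE 0.33). That list had adjusted p = 0.130, and 0.0585 with E18 replicate 1 alone.

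The E18 replicates differed in library profile. The mitochondrial ribosomal RNA mt-Rnr2 took 0.666% of UMIs in E18 replicate 1, 0.456% to 1.17% in the E14 and E16 replicates, and 0.0973% to 0.183% in E18 replicates 2 and 3 and at P1. With E18 replicate 1 alone, which must then be assumed to vary like the other ages, 92 genes passed (81 higher, 11 lower), 84 of them among the 2052, which were themselves called with that replicate included. Ppp1r27, Calb2, Myl1, Fabp3, Espn, Ccdc177, Ctnna1 and Rnf150 passed there, while Ccl21a (adjusted p = 0.0872), Rem2 (0.0784), Pgk1 (0.245), Atp5l (0.245), Bloc1s1 (0.490) and the other named genes that fell did not. The log2 difference shrank to 1.80 for Ccl21a, 1.61 for Pgk1, 1.02 for Atp5l and 0.60 for Bloc1s1. It stayed near its size for Rem2 (2.76), Tmie (-1.84), Igfbp2 (-1.65), Spock1 (-1.52), Gas1 (-1.43) and Prkg1 (-1.35), was larger for Uts2b (-3.07) and smaller for Rgs4 (-1.61). Glycolysis had a median of 0.76 in that replicate, with 5 of 18 genes up and adjusted p = 1.9e-10, calcium-binding proteins had 0.000228, axon guidance 0.00129 and transcription factors 0.0198, while adhesion had 0.222. The count of 2052 became 636 without E16 replicate 2, 687 without E16 replicate 3, 3359 without E18 replicate 1, 858 without E18 replicate 2 and 796 without E18 replicate 3, and 1335 with only both ages in the fit.

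The comparison of P1 with E18 spans birth, and both ages were dissociated with papain. In edgeR 0 genes rose and 1 fell, while 1149 of 12547 had an unadjusted p under 0.05 and DESeq2 called 23 higher and 2 lower. The gene that fell was Gm10320, a gene model chosen after its values were seen and outside the naming rule, with a log2 difference of -4.41 (SE 0.50, adjusted p = 0.00197). It had 4.47 and 4.64 CPM in both P1 replicates and 40.1 to 139 CPM at E18, and it lost its call without P1 replicate 1 (adjusted p = 0.142) or P1 replicate 2 (0.0856). Without the filter on low counts 73 genes passed, with only both ages in the fit 0, and without E18 replicates 2 and 3 162. Calb2 was at 1667 ± 240 CPM at E18 and 2440 ± 880 CPM at P1 (n = 2), a log2 difference of 0.56 (SE 0.41, adjusted p = 0.71). The parvalbumin gene Pvalb had a log2 difference of 0.73 (SE 0.23, adjusted p = 0.42) and the sodium channel gene Scn1a of 1.07 (SE 0.27, adjusted p = 0.26). Calcium-binding proteins were higher as a list (adjusted p = 0.0435, and 0.351 with an estimated correlation) with 0 of 15 members past the threshold. Type II markers were lower as a list (adjusted p = 0.0446, and 0.454 with an estimated correlation) with 0 of 7 past it, with Gata3 at -0.76 (SE 0.25) and Etv4 at -0.71 (SE 0.31). In fry 0 lists passed in this comparison.

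From E14 to P1 5447 of 12547 genes changed, 2808 higher and 2639 lower at P1, with 3 replicates against 2 and the enzyme changing too. Calb2 rose from 1.20 ± 1.10 CPM to 2440 ± 880 CPM (log2 10.95, SE 0.64, adjusted p = 1.3e-08) and Myl1 from 0.469 ± 0.461 to 106 ± 15.1 CPM (log2 7.63, SE 0.78). Ccl21a, with 0 counts at E14, was at least 187-fold higher at P1 against a floor of 3 counts over the group. Ratios with counting intervals were 918 (164 to 36340) for Ppp1r27, 287 (97.4 to 1395) for Cpne9, 250 (44.0 to 9952) for the desmosome protein gene Ppl, 181 (61.2 to 882) for Espn, 182 (31.8 to 7266) for the cadherin Cdh9, 122 (33.1 to 1019) for Gldn and 123 (33.3 to 1027) for Upk3a. Against the same floor, genes with 0 counts at P1 were at least 238-fold lower for Ppp1r17, 72.2-fold for Dio3, an enzyme that inactivates thyroid hormone, 52.2-fold for Rd3, 40.2-fold for Lmod1 and 35.3-fold for the transcription factor gene Neurod2. E14 exceeded P1 998 times for Ppp1r14a (interval 179 to 39440), 175 times for Nhlh1 (48.3 to 1448), 106 times for Fam212b (18.7 to 4187) and 96.8 times for Dock10 (26.6 to 802).

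Over this whole range 15 of 18 glycolysis genes rose, with Aldoc at 2.87 (SE 0.25) and Eno2 at 2.59 (SE 0.21), list adjusted p = 6.3e-06, and adjusted p = 0.205 with an estimated correlation. Of 24 synaptic vesicle genes 11 rose and 1 fell, 13 and 1 adjusted over the list alone. Syt7 was at 3.09 (SE 0.22) and Cplx1 at 1.86 (SE 0.22), with list adjusted p = 0.00894, and adjusted p = 0.539 with an estimated correlation. Of 31 axon guidance genes 15 fell and 3 rose, 16 and 3 adjusted over the list alone. Sema6d was at -5.18 (SE 0.47), Sema3a at -2.82 (SE 0.29) and Nrp1 at -2.24 (SE 0.31), with list adjusted p = 0.0251, and adjusted p = 0.351 with an estimated correlation. Of 33 neuronal transcription factors 18 fell and 7 rose, 19 and 8 adjusted over the list alone. Etv4 was at -3.05 (SE 0.29) and Pou4f1 at -2.55 (SE 0.27), with list adjusted p = 0.0251, and adjusted p = 0.454 with an estimated correlation. Cell cycle genes fell (7 of 17, Ccnd1 at -2.68, SE 0.32, list adjusted p = 0.0120, 0.454 with an estimated correlation), as did all 5 neuroblast markers (Nhlh2 at -3.84, SE 0.40, list adjusted p = 0.00189, 0.454 with an estimated correlation). Type IA markers rose in 4 of 6 cases (Mdga1 at 1.95, SE 0.32, list adjusted p = 0.0229, 0.351 with an estimated correlation). S100b rose by 6.53 (SE 0.40) and Dcn by 3.07 (SE 0.34), while the glial Mbp fell by 1.52 (SE 0.52). Haemoglobin Hba-a1 fell by 6.77 (SE 0.79). The mitochondrial mt-Rnr2 took 0.535% to 1.17% of UMIs in the E14 replicates and 0.152% and 0.183% at P1.

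At E16 the apical and basal portions were compared, which asks how neurons differ along the cochlea, where development runs from base to apex. Uts2b was higher in the apex, at 54.1 ± 22.7 CPM against 3.43 ± 2.56 CPM (n = 3 each), a log2 difference of apex minus base of 4.23 (SE 0.43, adjusted p = 7.8e-05). Etv4, a transcription factor induced by FGF signalling, was at 93.1 ± 15.3 against 13.3 ± 3.43 CPM (log2 2.80, SE 0.21). The phosphatase Dusp6, another FGF target, was at 25.7 ± 3.36 against 2.81 ± 1.03 CPM (3.22, SE 0.30), and Neurod1 at 43.8 ± 9.67 against 8.84 ± 2.65 CPM (2.36, SE 0.25). S100b was higher in the base, at 62.4 ± 8.13 CPM against 2.62 ± 1.77 CPM in the apex (log2 -4.70, SE 0.33, adjusted p = 5.5e-06), as was the adhesion protein gene Cntn5, at 1169 ± 120 against 216 ± 63.9 CPM (-2.45, SE 0.20). In total 309 of 11340 genes passed, 139 higher in apex and 170 higher in base. With the replicate number as a block 1223 passed (527 and 696), with all 309 among them.

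Other genes higher in the apex were Sobp (log2 3.03, SE 0.31), the cadherin Cdh13 (2.83, SE 0.28), the matrix protein gene Hmcn1 (2.60, SE 0.26), the adhesion gene Negr1 (2.55, SE 0.37), Rgs4 (2.34, SE 0.25) and Igfbp2 (2.25, SE 0.26). Other genes higher in the base were Plekha7 (-3.25, SE 0.29), the copine Cpne9 (-2.44, SE 0.31), Dcn (-2.40, SE 0.21), Dok1 (-2.31, SE 0.25), the synaptic adhesion gene Cadm2 (-2.19, SE 0.19), the protocadherin Pcdh20 (-2.12, SE 0.31), Mab21l2 (-2.04, SE 0.22) and the adrenergic receptor Adra2c (-2.03, SE 0.29). All of these kept their call with DESeq2, in the blocked fit and without any library. Uts2b lies on chromosome 16 from 27353322 to 27370239 and S100b on chromosome 10 from 76253853 to 76261159, both annotated as protein coding in mm10.

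Neuroblast markers were higher in the apex as a list, with 2 of 3 past the threshold and 3 adjusted over the list alone, among them Nhlh2 at 1.47 (SE 0.17) beside Neurod1, list adjusted p = 7.9e-07, and adjusted p = 0.107 with an estimated correlation. Type IB/IC markers were higher in the apex, with Calb1, calbindin, past the threshold at 1.06 (SE 0.20) and 4 of 5 adjusted over the list alone, list adjusted p = 0.00189, and adjusted p = 0.277 with an estimated correlation. Type IA markers were higher in the base, with 2 of 6 past it and 3 adjusted over the list alone. Pcdh20 was at -2.12 and Calb2 at -2.15 (SE 0.51), with list adjusted p = 2.1e-04, and adjusted p = 0.107 with an estimated correlation. Calcium-binding proteins were higher in the base in 4 of 14 cases and lower in 1, 5 and 1 adjusted over the list alone. Vsnl1 was at -1.64 (SE 0.19) and Necab1 at -1.33 (SE 0.15), with list adjusted p = 0.0122, and adjusted p = 0.207 with an estimated correlation. Synaptic vesicle genes were higher in the base as a list (adjusted p = 1.5e-04, and 0.107 with an estimated correlation), with Syt2 at -2.31 (SE 0.55) and Cplx2 the other way at 1.03 (SE 0.15), and 5 and 1 of 24 adjusted over the list alone. Glycolysis was higher in the base with 0 of 18 members past the threshold (list adjusted p = 0.0342, and 0.408 with an estimated correlation). Otic mesenchyme markers were higher in the base as well (adjusted p = 0.0252, and 0.408 with an estimated correlation), with Dcn past the threshold, Col1a2 at -1.60 (SE 0.49) and Pou3f4 at 0.65 (SE 0.24). Neuronal transcription factors passed only in the blocked fit (adjusted p = 0.0785 without the block and 0.00862 with it). Without the block, no list passed in camera with an estimated correlation, the lowest adjusted p being 0.107.

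The count of 309 became 127 without apex replicate 2, 184 without base replicate 2, 165 without base replicate 3 and 172 with cells of at least 5000 UMIs, and 561 with no filter on low counts. In fry 4 of the 7 lists passed.

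**Figure D2:**
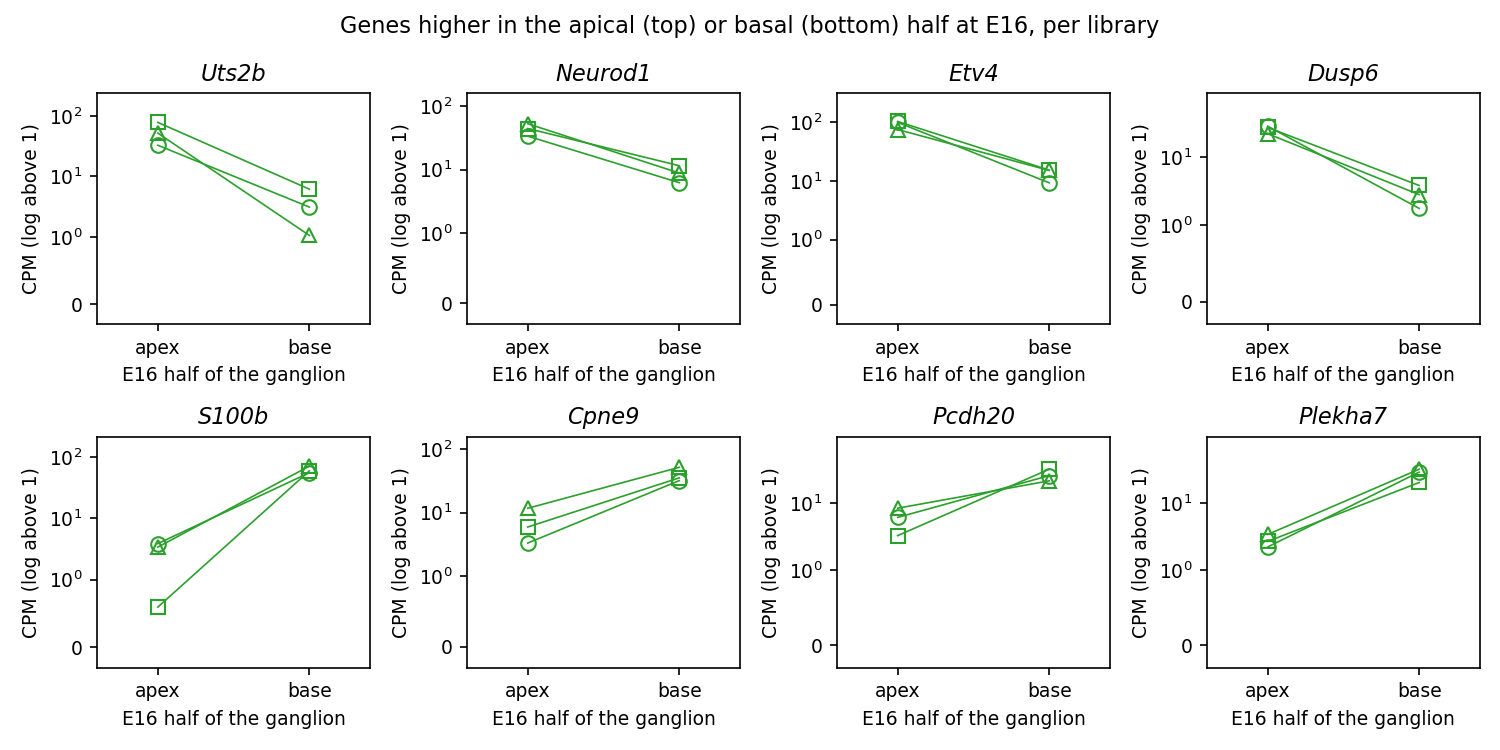
Expression in CPM (y axis, log scale above 1) of 8 genes in the apical and basal E16 libraries (x axis), with 1 marker per library (circle, square and triangle for replicates 1, 2 and 3) and a line between libraries of 1 replicate number. Uts2b had a mean of 54.1 CPM in apex and 3.43 in base, and S100b 2.62 in apex and 62.4 in base.

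Clusters of the E16 cells were also compared between the portions, after 1181 genes called with or without the block, among the 11340 tested without it, were taken out of the clustering. Other genes called only with the block stayed in. A cluster of 206 cells, marked by Uts2b, Neurod1, Igfbp2 and Rgs4 although these were taken out, held 11.8% ± 2.46 (SD, n = 3) of the apical and 3.41% ± 0.998 of the basal cells. A cluster of 617 cells marked by Lypd1, Pou4f1, Pvalb and Runx1 held 21.9% ± 2.23 of the apical and 28.2% ± 2.07 of the basal cells. A cluster of 466 cells marked by Cdkn1a, Tle4 and Prph held 21.1% ± 2.53 and 15.7% ± 2.19. Each of these 3 had an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. The other 4 clusters had exact p of 0.2 to 0.3. Within replicate numbers, 6 of the 7 clusters, the first 3 included, differed with 1 sign in all 3 pairs, an exact sign flip p of 0.25, so by that measure the first 3 do not stand apart from the others. Clusters made with all variable genes named 9.63% ± 6.72 of apical and 34.1% ± 2.71 of basal cells type IA, 22.9% ± 1.19 and 28.3% ± 3.67 type IB/IC, and 0.0672% ± 0.116 and 3.07% ± 2.10 type II. However, 16 of the subtype and neuroblast markers were themselves among the 1181 genes. These shares are therefore not independent of the gene result. Differences taken within replicate numbers had an exact sign flip p of 0.25 for each class, the smallest that 3 differences allow. Type II went the other way at resolution 1.4 (8.27 points higher in apex) and in list classes (5.56 points), and type IB/IC in list classes (6.59 points). For type IA the difference of apex minus base was -24.5 points in the main clusters, -12.5 in list classes and -3.23 at resolution 1.4. At resolution 0.6 no cluster was named type IA.

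The subtype programmes were followed through their list scores, which asks whether type IA, IB/IC and II neurons part before birth. The correlation across cells between type IA and type IB/IC scores had a mean over replicates of 0.0907 ± 0.177 (SD, n = 3) at E14, -0.273 ± 0.0706 (n = 3) at E16, -0.465 ± 0.105 (n = 3) at E18 and -0.546 ± 0.0311 (n = 2) at P1. The E14 mean was 0.125 thinned to 3000 UMIs and 0.256 unthinned. Type IB/IC and type II scores went from 0.00246 ± 0.245 to -0.475 ± 0.0694, -0.542 ± 0.0403 and -0.530 ± 0.0403. Type IA and type II scores had positive means, of 0.257 ± 0.0633, 0.192 ± 0.0331, 0.184 ± 0.195 and 0.378 ± 0.0213. For type IA with IB/IC, all replicates at E16, E18 and P1 lay below the central 95% of 100 random list pairs, while at E14 0 of 3 did and replicate 2 lay above it, at 0.294. For IB/IC with II, all replicates at E16, E18 and P1 lay below it. At E14 replicate 2 lay above it, at 0.286. E14 replicates 1 and 3 lay below it at -0.130 and -0.148, but were at -0.0398 and 0.0693 thinned to 3000 UMIs and at 0.0711 and 0.209 unthinned, so their sign depends on the thinning. For IA with II, all replicates lay above it except E18 replicate 2, which was inside it at -0.0369. That value rests on 119 of 323 cells, and was 0.279 thinned to 3000 UMIs and 0.266 unthinned. The trend with age order over 11 replicates had Pearson r = -0.895 (exact permutation p = 1.4e-04, adjusted p = 0.00296 over 21 tests) and Spearman rho = -0.919 (exact permutation p = 1.7e-04) for IA with IB/IC, and r = -0.750 (exact permutation p = 0.00353, adjusted p = 0.0371) and rho = -0.820 (exact permutation p = 0.00310) for IB/IC with II. For IA with II the trend was 0.246 (exact permutation p = 0.482) and rho 0.436 (exact permutation p = 0.182). Without both P1 replicates, the 2 farthest in age, r was -0.900 (exact permutation p = 0.00238), -0.819 (exact permutation p = 0.00238) and -0.288 (exact permutation p = 0.498) for the 3 pairs. With only the replicates of E14 and E16 and E18 replicate 1, grouped by the share of mt-Rnr2 alone, r was -0.900 (exact permutation p = 0.0143), -0.822 (exact permutation p = 0.0286) and -0.216 (exact permutation p = 0.657). Differences between single ages had exact permutation p values of 0.1 or more, the smallest these designs allow. Thinning to 5000 UMIs left out 831 of 1637 cells at E14, 853 of 2478 at E16, 225 of 862 at E18 and 36 of 464 at P1.

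**Figure D3:**
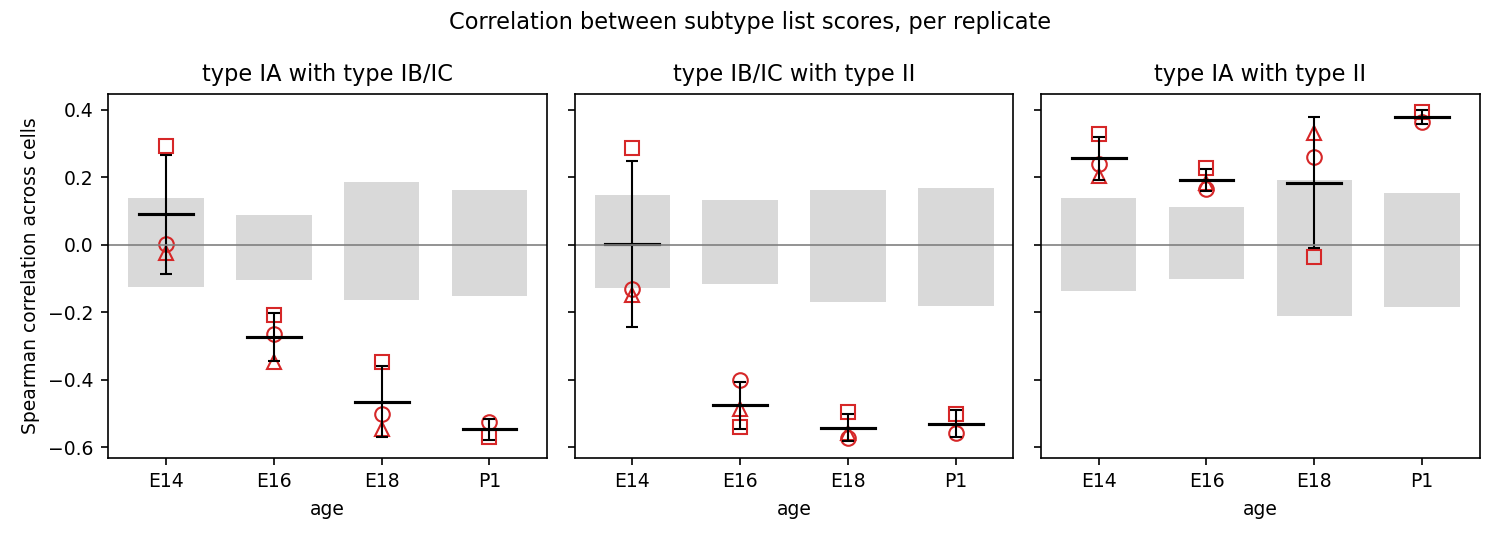
Spearman correlation across cells between scores of 2 subtype lists (y axis) by age (x axis) for 3 pairs of lists, with 1 marker per replicate, the mean with SD bars, and grey bands for the outermost limits of random list pairs. For type IA with type IB/IC the mean was 0.0907 at E14 and -0.546 at P1.

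Type II neurons, a small class that contacts outer hair cells, were compared with type I neurons through list classes, on genes outside the lists. At P1 (39 against 167 cells in 2 libraries) Tac1, the precursor of substance P, was at 176 ± 74.3 CPM in type II-like and 9.26 ± 10.4 CPM in type I-like cells (log2 4.66, SE 0.39, adjusted p = 3.8e-29 in edgeR, 6.4e-07 in DESeq2). With 2 libraries and a library block, the edgeR fit has almost nothing from which to estimate spread between libraries. Its small p is thus no measure of that spread. Efna5, an ephrin ligand, had 0 counts in type I-like cells and was at least 54.2-fold higher in type II-like cells, while Espn had 0 counts in type II-like cells and was at least 16-fold lower. Ratios with counting intervals were 64.7 (16.4 to 558) for Slc9a3r1, 50.1 (12.4 to 437) for Fstl5 and 27.1 (6.14 to 248) for Iqgap2, and in favour of type I 36.7 (6.49 to 1458) for Bhlhe22, 21.3 (3.73 to 852) for Synm and 12.4 (3.33 to 103) for the potassium channel Kcna1. Ppp1r27 was lower in type II-like cells at -3.53 (SE 0.43). At E16 (242 against 759 cells in 6 libraries) Efna5 (log2 3.88, SE 0.34), Iqgap2 (3.17, SE 0.53), the BMP antagonist Nog (3.02, SE 0.44), Tuba4a (1.59, SE 0.15) and Tmem132e (1.54, SE 0.17) were higher in type II-like cells. Mgat4c (-3.52, SE 0.36), Zeb2 (-3.18, SE 0.31), Cit (-2.96, SE 0.42) and Cdk14 (-2.95, SE 0.17) were lower, and Grxcr1, with 0 counts in type II-like cells, was at least 12.3-fold lower. Most type I-like cells were type IB/IC-like, 521 against 238 type IA-like cells at E16 and 119 against 48 at P1. Mgat4c at E16, and Espn, Bhlhe22 and Cdk14 at P1, were also lower in type IA-like than in type IB/IC-like cells. Genes lower in type II-like cells may thus mark type IB/IC rather than all type I neurons.

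Between type II-like and type I-like cells 65 genes passed at E14 (33 higher, 32 lower), 543 at E16 (252, 291), 385 at E18 (174, 211) and 405 at P1 (175, 230). They rest on 3, 6, 2 and 2 libraries, and the 6 at E16 are portions of 3 replicates. The counts therefore cannot be ranked between ages. Classes from random lists of matched expression gave at most 28 genes at E16, 8 at E18 and 5 at P1, but up to 414 at E14, where 3 of 10 random sets gave as many as the real lists. DESeq2 called 1, 202, 39 and 36 genes, and edgeR with no library block 7, 105, 0 and 0 (0 with 261 and 351 genes at an unadjusted p under 0.05). Of the P1 genes named above, Espn (adjusted p = 1.00), Bhlhe22 (0.0563), Synm (0.530) and Kcna1 (0.447) did not pass in DESeq2, which gave no value for Iqgap2. With equal cells and UMIs per class the counts were 3, 25, 6 and 13. They were 29 to 38 at E14 without any 1 replicate and 328 at E16 without apex replicate 3. At E18 and P1, where leaving out 1 of 2 usable libraries leaves no replicate, all ages were put in 1 fit, which also tests more genes. That fit gave 319 genes at E18 with all libraries and 37 and 216 without replicate 1 or 2, and 339 at P1 with all libraries and 108 and 167 without replicate 1 or 2. At E16 the type II-like class held 19 of the 35 cells of the type II cluster among its 242 cells, so it is broader than that cluster.

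Type IA-like and type IB/IC-like cells, classes of type I neurons, were compared in the same way. At P1 (48 against 119 cells in 2 libraries) Myl1 had 0 counts in type IB/IC-like cells and was at least 77.8-fold higher in type IA-like cells. Prrx2 was higher at 166 ± 17.9 against 26.9 ± 0.955 CPM (log2 2.70, SE 0.31), as were Necab1 (3.80, SE 0.70) and Qpct (2.50, SE 0.63). Nexn had a ratio of 29.8 (7.34 to 262). Type IB/IC-like cells had more Espn (log2 IA minus IB/IC -3.76, SE 0.44) and Cdk14 (-3.09, SE 0.37). In favour of type IB/IC the ratios were 18.8 (6.31 to 92.2) for Slc17a6, the vesicular glutamate transporter, 18.4 (6.19 to 90.4) for Bhlhe22 and 17.0 (2.89 to 684) for Mgat4c. At E16 (229 against 371 cells in 5 libraries) Necab1 (4.08, SE 0.31), Dok5 (3.19, SE 0.43), Kctd12 (2.86, SE 0.19), Palmd (2.69, SE 0.54) and the matrix protease Mmp14 (2.67, SE 0.39) were higher in type IA-like cells. Sema3a (-3.70, SE 0.29), Mgat4c (-3.38, SE 0.38), Slc17a6 (-3.33, SE 0.28), Rnf150 (-3.08, SE 0.33) and Trim36 (-3.05, SE 0.43) were higher in type IB/IC-like cells.

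Between these classes 44 genes passed at E14 (25 higher in type IA, 19 lower), 534 at E16 (240, 294), 441 at E18 (209, 232) and 180 at P1 (75, 105). They rest on 3, 5, 3 and 2 libraries, and those at E16 are portions of 3 replicates, so the counts cannot be ranked between ages. Random lists gave at most 5 at E16, 5 at E18 and 31 at P1, and up to 146 at E14, where 2 of 10 sets gave as many. DESeq2 called 1, 187, 84 and 38 genes, edgeR with no library block 5, 184, 39 and 5, and equal cells and UMIs per class gave 1, 40, 6 and 2. At P1 DESeq2 did not call Myl1 (adjusted p = 0.660) and Slc17a6 (0.471) and gave no value for Nexn, Necab1, Qpct and Mgat4c. The counts were 22 and 13 at E14 without replicate 1 or 3, 332 at E16 without base replicate 3, and 168 at E18 without replicate 1. At P1 the fit of all ages together gave 169 with all libraries, and 50 and 73 without replicate 1 or 2.

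The genes that separated the classes at P1 were then looked up in the earlier libraries. Of the P1 genes between type IA and IB/IC, 67.6% (95% interval 59.3 to 75.2) had the same direction at E14, 94.8% (90.4 to 97.6) at E16 and 97.8% (94.4 to 99.4) at E18, against 55.5%, 61.5% and 64.5% of all genes tested. Past the threshold in that direction were 7.75%, 69.4% (120 of 173) and 77.5% (138 of 178). Of the P1 genes between type II and type I, 63.8% (58.3 to 69.1), 79.8% (75.5 to 83.8) and 94.7% (92.0 to 96.8) had the same direction, against 52.1%, 57.9% and 63.4% of all genes, and 6.92%, 41.1% and 58.7% passed. Genes are not independent replicates, so these intervals cover counting only. The number of libraries differs between ages, and apical and basal libraries of E16 were counted apart. Shares past the threshold therefore depend on the libraries of each age as well. With P1 genes called without replicate 1 or 2, in the fit of all ages together, the shares past the threshold at E14 were 13.6% and 12.5% for type II against I, and 15% and 17.0% for IA against IB/IC.

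**Figure D4:**
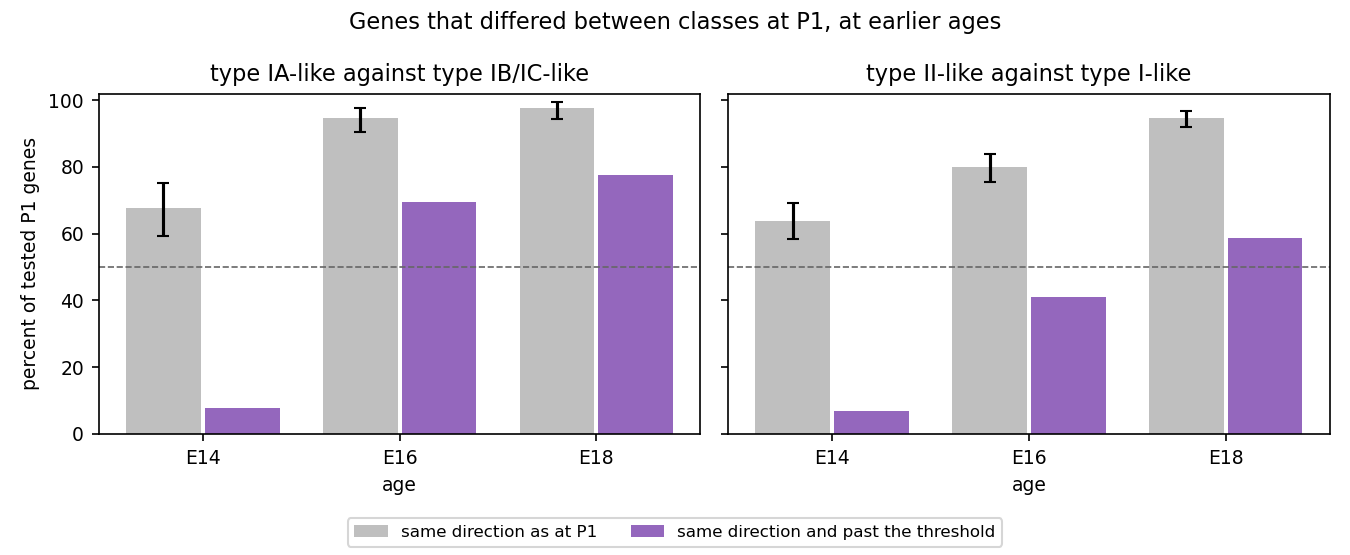
Percent of the genes called between classes at P1 (y axis) that had the same direction, with exact 95% intervals, and that passed the threshold in the same direction, by earlier age (x axis), for type II against type I and type IA against type IB/IC. The dashed line marks 50%, and the shares with the same direction at E18 were 94.7% and 97.8%.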

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

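The tests of the dissociation enzyme, of glycolysis, of depth and of regrouped replicates were chosen after the result was seen, while those of gene model share, progress with age, the age axis in the apex and mesenchyme were written before their values were computed. After the first output the reading of gene model share, of the enzyme among E18 libraries and of mesenchyme was changed, an SD was added to that of progress, and the test of depth was replaced, as stated beside each.

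The difference between list classes itself differed between ages in several cases, each as a test of the interaction in edgeR. Between type II-like and type I-like cells 52 genes differed between E16 and E14 (13 more positive, 39 more negative), 43 between E18 and E16 (14 and 29) and 106 between P1 and E16 (30 and 76). Between P1 and E18 0 genes differed in edgeR, with 347 of 7987 at an unadjusted p under 0.05, and this difference was not tested in DESeq2. Between type IA-like and type IB/IC-like cells 94 genes differed between E16 and E14 (22 and 72), 1 between E18 and E16 and 4 between P1 and E16, while 0 differed between P1 and E18, with 304 of 6799 at an unadjusted p under 0.05. The genes that follow were chosen after their values were seen. The 1 gene was Pvalb, parvalbumin, whose difference was 1.15 higher on the log2 scale at E18 than at E16. For E16 minus E14 the same difference of Pvalb had gone the other way, at -1.49 (interaction test in edgeR, adjusted p = 1.5e-17). The 4 genes were Pvalb (1.36), Hs3st1 (-2.07), Cdkn1a (-1.40) and Brinp1 (-1.46) for P1 minus E16. These classes are ranges of a score, and no cluster was named type II at E14, where the type II-like class had 84 cells. That class held 19 of the 35 cells of the type II cluster among 242 cells at E16, 23 of 31 among 80 at E18 and 16 of 16 among 39 at P1, so its make-up differed between ages.

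E18 replicate 1 lay nearer the E16 replicates (correlations of 0.952 to 0.966) than E18 replicates 2 and 3 did (0.909 to 0.932). A library or sequencing batch shared with E14 and E16 would put its share of UMIs in gene models of the TEC class within their range of 0.269% to 0.481%. The value was 0.212%, outside the range but by less than the SD of 0.0716 over those replicates, so this test cannot tell, a reading set after the value was seen, as the rule written before would have ruled the batch out. A litter younger than both others would have made less progress along the genes between E14 and E16, but its progress of 1.28 was above the 1.18 of replicate 2 by 0.0974, more than the SD of 0.0774 over the E16 replicates, and above the 1.26 of replicate 3 by 0.0183, which speaks against that cause by the rule written before, while a stricter reading tried after the values were seen, above both by more than the SD, would leave it open. The labels name papain for every E18 library, so the enzyme cannot part replicate 1 from replicates 2 and 3, between which 204 genes differed; the limit first set, 1 in 20 of the 2052 genes changed with age, was not reached, with 1 such gene, and was set aside after the values were seen, since genes that differ among E18 libraries need not change with age.

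Glycolysis genes were higher at E18 than at E16, with a median log2 difference of 0.75. A batch of E18 replicates 2 and 3 would leave little of it in replicate 1, where the median was 0.76, which speaks against that cause. The enzyme would leave the list unchanged between E14 and E16, both made with trypsin, and the median there was 0.11, with a list adjusted p of 0.0484 at the preset correlation and 0.454 with an estimated one, so the enzyme could still contribute and this test cannot tell.

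Genes between apex and base followed the age axis: 91.9% (95% interval 88.2 to 94.7, 283 of 308) were moved in apex the way E14 differs from P1, against 65.9% of all tested genes. This fits apical cells at an earlier stage, as far as a count of directions goes. Type IA markers were higher in base than in apex and also higher at P1 than at E14. The count therefore cannot tell an earlier stage from another mix of subtypes, which was not tested. Cells under 5000 UMIs do not account for it as a whole: with cells of at least 5000 UMIs in both comparisons 172 genes passed, 165 of them among the 309, and 90.1% (84.7 to 94.1) of the 172 went that way, against 62.8% of all genes tested there, a test that replaced 1 of kept directions in the same cells, which decides nothing. The floor left 11 cells in base replicate 2 and does not make depth equal above it. Differences of depth as such are therefore not excluded, and the shared genes come from part of the same cells. Mesenchyme or glia in the basal tissue would raise their markers, and apart from Dcn and S100b the median of base minus apex was 0.15. The rule written before would have ruled this cause out, but members went both ways, from 1.60 for Col1a2 to -0.65 for Pou3f4, so the reading was set to undecided after the values were seen. Dcn and S100b also marked E16 clusters named type IA and type IB/IC, so they are not signs of other cells alone.

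Regrouping the replicates gave only 10 splits per comparison, too few for a test: the real split, 1 of the 10, gave 1771 genes between E16 and E14, 2052 between E18 and E16 and 309 between apex and base, and the highest other counts were 0, 2 and 1.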

How the results depend on the processing

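The fits without E18 replicates 2 and 3, without P1 in the programme trends and with only E14, E16 and E18 replicate 1 were chosen after the result was seen. The class fits with all ages together were also chosen then, and the others were planned. Of the values that answer the questions, 206 were labelled as kept, 98 as moved and 6 as reversed. The limit of 1.5 times was set for counts. Differences of shares were labelled as kept on their sign alone, whatever their size. Trends were labelled as kept when their sign held and their p stayed on the same side of the threshold. A fit with all deposited cells was among the settings, but it repeated the main fit, so its values were kept by construction. Of single genes and lists, 994 stayed the same, 13 became stronger and 50 weaker, of which 32 weaker calls came from camera with an estimated correlation. Depth limits genes with few counts, and the fits that leave a single replicate at an age assume that it varies like the others. A margin of 0.75 at P1, and for type IA at E14, left too few cells and was not fitted. Except where fewer samples, cells or genes explain it, the cause was not tested.

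Between E16 and E14, 1771 genes became 1008 with cells of at least 5000 UMIs, and 1150 to 1469 with a replicate left out. Between E18 and E16, 2052 became 1335 with only both ages in the fit, 636 to 3359 with a replicate left out (636 without E16 2, 687 without E16 3, 858 without E18 2, 796 without E18 3) and 92 without E18 replicates 2 and 3. Between P1 and E18, 1 became 25 in DESeq2, 73 with no filter, 0 with only both ages, 0 to 1 with a replicate left out and 162 without E18 replicates 2 and 3. Between P1 and E14, 5447 became 3810 to 4898 with a replicate left out.

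With the replicate number as a block, 309 genes between apex and base became 1223, and all 309 were called again. Each portion correlated best with the portion of its own number, a hint from the data that numbers mark shared litters. Replicate numbers of different ages are different litters, and that block gave 1803 genes between E16 and E14 and 1855 between E18 and E16. Between apex and base 561 passed with no filter, 172 with cells of at least 5000 UMIs and 127 to 339 with a library left out.

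For type II-like against type I-like cells at E14, E16, E18 and P1, the counts 65, 543, 385 and 405 became 1, 202, 39 and 36 in DESeq2, 7, 105, 0 and 0 with no library block, and 3, 25, 6 and 13 with equal cells and UMIs. They were 153 at E14 with margin 0.25, 29 at E14 and 246 at E16 with margin 0.75, and 265 at P1 with no filter. With a replicate left out they ranged from 29 to 38, 328 to 562, 37 to 216 and 108 to 167. The E18 and P1 ranges come from a fit of all ages together, since 1 library would be left, and with all libraries that fit gave 319 and 339. For type IA against type IB/IC, 44, 534, 441 and 180 became 1, 187, 84 and 38 in DESeq2, 5, 184, 39 and 5 with no block, and 1, 40, 6 and 2 with equal cells. They were 932 at E16 with margin 0.25, and 305 at E16 and 147 at E18 with margin 0.75. With a replicate left out they ranged from 13 to 42, 332 to 516, 168 to 334 and 50 to 73, the last from the fit of all ages together, which gave 169 with all libraries.

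The share of P1 genes past the threshold at E14, E16 and E18 was 19.2%, 66.3% and 93.9% for type II with the 100 smallest p, 14.0%, 52.4% and 70.0% with margin 0.25, and 12.5% to 13.6%, 43.8% to 61.8% and 73.1% to 82.3% without a P1 replicate, with P1 genes from the fit of all ages together. For type IA it was 84.4% at E16 and 93.9% at E18 with the 100 smallest p, 13.5%, 81.9% and 90.2% with margin 0.25, and 15% to 17.0%, 84.1% to 89.6% and 91.5% to 92% without a P1 replicate, in the same fit. The share with the same direction ranged from 66.4% to 68.2%, 82.9% to 89.8% and 95.2% to 99.4% for type II, and from 77.5% to 79.2%, 95.7% to 95.8% and 94% to 100% for type IA.

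The trend of type IA with type II scores, 0.246, reversed to -0.0411 with Pearson's correlation across cells, -0.288 without P1 and -0.216 with only E14, E16 and E18 replicate 1, and ranged from 0.0525 to 0.632 with a replicate left out. The other trends ranged from -0.930 to -0.881 for type IA with IB/IC and from -0.793 to -0.721 for IB/IC with II. The shares of apex minus base reversed for type IB/IC, from -5.35 to 6.59 points with list classes, and for type II, from -3.01 to 5.56 with list classes and 8.27 at resolution 1.4. For type IA the difference shrank from -24.5 to -12.5 points with list classes and to -3.23 at resolution 1.4. Resolution 0.6 named no type IA cluster. With a library left out the shares of apex minus base ranged from -28.3 to -22.4 for type IA, -6.52 to -3.24 for IB/IC, -3.90 to -1.85 for II and 30 to 36.5 for unnamed cells.

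With an estimated correlation camera called 0 lists in each of the 5 comparisons, against 11, 5, 2, 7 and 7. In fry 0 lists passed between P1 and E18, 12 between P1 and E14 and 4 between apex and base. Without E18 replicates 2 and 3, 8 lists passed between E18 and E16.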

Other observations

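The comparison of gene pairs in single cells was chosen after the result was seen. Cells with both Calb2, a type IA marker, and Lypd1, a type IB/IC marker, were counted at each age. After thinning to 5000 UMIs they were 0.248% of cells at E14, 4.99% at E16, 22.5% at E18 and 37.2% at P1, against 0.413%, 11.7%, 31.8% and 44.3% if both genes were independent, with odds ratios of 0.439, 0.203, 0.139 and 0.118. Calb2 had at least 1 UMI in 0.869%, 25.9%, 70.6% and 77.1% of cells. With 806 cells kept at E14, the odds ratio there rests on very few cells and sets no starting point for a trend. Cells were pooled over the replicates of an age, at E16 over apex and base too, and no interval was computed. Free RNA limits such shares: no other cell type is in the files to measure it, but Hbb-bs of red blood cells was found in 5.47% to 90.6% of neurons per library.

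At E14 clustering gave a neuroblast cluster of 324 cells, which held 15.1%, 29.6% and 18.1% of the cells of the 3 replicates. No cluster at E16, E18 or P1 was named so.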
